A study of Mus musculus with 4 samples.

How the data were processed

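Total RNA of salivary gland tissue from C57BL/6 mouse embryos was sequenced after ribosomal RNA depletion, in 2 libraries labelled wild-type and 2 labelled Irf6 null. Per the submitters' processing notes, bcl2fastq 1.8.4 and RSEM were used with the GRCm38 (mm10) mouse genome; the aligner, the annotation release and the strand setting are not given in the sources used here. The deposited count table holds RSEM expected counts per gene in 4 columns, matched to the samples by the sample numbers in the labels; 7780 genes have a non-whole count, because reads shared between genes are split. Per the file headers, a deposited comparison table holds the authors' log2 fold change, a likelihood ratio score, p-values and adjusted p-values for 166 genes; neither the tool nor the direction is named in it. A further deposited sheet holds other content, a list of gene symbols headed Mist1 targets with no measurement, and how it was chosen is not stated.

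Gene identifiers were matched to the GENCODE M21 annotation of GRCm38 for coordinates and gene classes, and 47310 of them matched. Where a symbol had several identifiers, the one with the highest total count stood for it in gene lists.

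Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3, with the filter filterByExpr by group, TMM scaling, the quasi-likelihood F test on genotype alone and Benjamini-Hochberg adjustment over the 17099 genes kept, at a threshold of 0.05. The TMM factors were 1.18, 1.17, 0.96 and 0.76 for wild-type 1, Irf6 null 1, wild-type 2 and Irf6 null 2. The SE of a log2 fold change is its size over the root of the F statistic. Expression is given as CPM after TMM scaling, from the rounded counts. Of 36 gene lists, 34 had at least 5 tested members. They were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, and beside it with an estimated correlation and with fry. The 36 lists held 694 different genes, of which 648 were tested. The groups, the tests, the lists, the rule for named genes and the alternatives were fixed before the data were examined.

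The rule named Irf6 first with every library's value. It then named up to 12 genes per direction with the largest fold change among those past the adjusted threshold with non-overlapping groups and a mean of at least 5 CPM, leaving out predicted gene models and pseudogenes. It then named up to 4 members of each list past the threshold or, where none passed, the 2 with the highest mean expression, as values. From the authors' deposited table it took counts and the 3 largest and 3 smallest fold changes. No gene passed the threshold, so other genes named were chosen after their values were seen, as stated beside them. Sex chromosome genes served as library checks.

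Depth ranged from 9676159 to 20516712 counts per library. A ratio involving few counts is given with a 95% interval from the conditional binomial distribution, or as a lower bound against a floor of 3 counts over the group; these cover counting error only. With 2 libraries per group the tests rest on few degrees of freedom, with a biological coefficient of variation of 37.1% across genes.

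The tests were tried on simulated counts for the 17099 genes of this comparison, drawn from the real means, dispersions and library sizes. Of these genes, 200 were changed, 50 for each size of change, each with a mean of at least 5 CPM. Genes were drawn independently and with no shift along the replicate number. The shares recovered therefore need not hold for the real libraries. The quasi-likelihood test recovered 4% of genes changed by a log2 fold of 1, 52% at 2, 94% at 3 and 100% at 5, all with the right sign, and 14 of its 139 calls were unchanged genes. The likelihood ratio test made 54 such calls out of 198 and DESeq2 58 out of 206. In a further simulation with a lower spread, assumed equal for all genes, the quasi-likelihood test recovered 86% at a log2 fold of 1 and 100% at 2, with 8 such calls out of 201, against 7 out of 200 for the likelihood ratio test and 6 out of 195 for DESeq2. In a simulated list test, a list of shifted genes was called by camera and 0 of 50 unchanged lists were. Its genes were also independent, so it could not show how the preset correlation does where the genes of a list move together. In the lists called below, the estimated correlation ranged from 0.0026 for FGF signalling to 0.97 for adipocyte genes.

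The alternatives were RLE scaling, library size alone, DESeq2 1.42.0, limma-voom, no filter, a stricter filter, the replicate number as a block, each library left out in turn, transcript classes left out (mitochondrial, ribosomal, haemoglobin and small non-coding RNA), stricter thresholds, and the other list tests. Alternatives on pseudocounts did not apply, since the table holds counts. The likelihood ratio test and the restriction to protein-coding genes were added after seeing the data. Marker lists for thyroid, airway, early suprabasal, late cornified and wound-type keratin genes were also added after seeing the data and serve only in the closing observations.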

Results

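RNA was measured by sequencing in salivary gland tissue of mouse embryos labelled E14.5, in 2 libraries labelled wild-type and 2 labelled Irf6 null. Irf6 encodes an interferon regulatory factor family transcription factor that is needed for keratinocyte differentiation. The series asks what this factor does in salivary gland development, and the design calls the libraries of each genotype biological replicates from littermates. The total estimated count was 20099452 in the library labelled wild-type 1, 9676159 in wild-type 2, 20000702 in Irf6 null 1 and 20516712 in Irf6 null 2. After a filter on low counts, 17099 genes were tested. Unless stated otherwise, expression is given as CPM, the count scaled to library size with TMM factors, and fold changes are the libraries labelled Irf6 null relative to those labelled wild-type.

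The targeted gene itself went against the labels. Irf6 (ENSMUSG00000026638, GRCm38 chromosome 1, 193153111 to 193172023, plus strand) stood at 6.44 CPM in the library labelled wild-type 1 and 4.34 CPM in wild-type 2, but at 41.4 CPM in the library labelled Irf6 null 1 and 40.0 CPM in Irf6 null 2. The corresponding estimated counts were 153, 40, 963.93 and 619.92. The group means were 5.39 ± 1.48 CPM (SD, n = 2) under the wild-type label and 40.7 ± 0.95 CPM (SD, n = 2) under the Irf6 null label, a log2 fold change of 2.90 (SE 0.29). In edgeR's quasi-likelihood test the unadjusted p was 0.000111 and the adjusted p over all genes was 0.474, so the difference did not pass the adjusted threshold although the libraries of the groups did not overlap. With DESeq2 the same gene passed, at an adjusted p of 1.5e-10, within a range from 4.3e-14 to 0.9998 over the alternatives. The counts are totals per gene and do not separate the targeted part of Irf6 from the rest. Every direction given here follows the labels as deposited, and each should be read with the Irf6 values in mind.

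**Figure D1:**
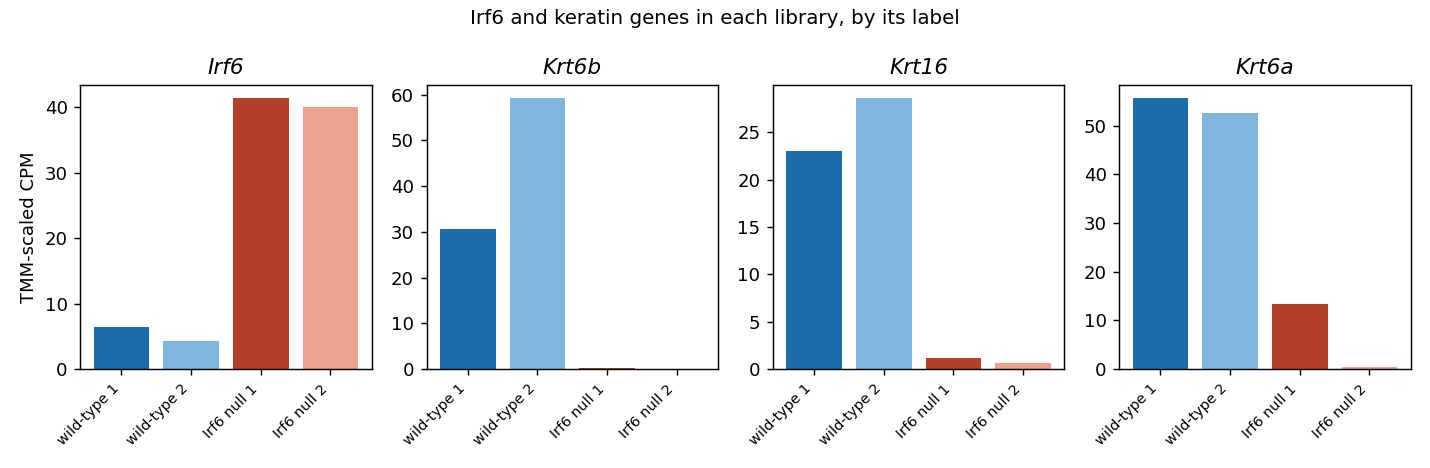
Bars give TMM-scaled CPM (y axis, linear, from 0) of Irf6, Krt6b, Krt16 and Krt6a in each of the 4 libraries, named on the x axis by their labels; there is 1 value per library and no error bar. Irf6 is at 6.44 and 4.34 CPM in the libraries labelled wild-type and at 41.4 and 40.0 CPM in those labelled Irf6 null, while the 3 keratin genes are lower in both libraries labelled Irf6 null.

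The comparison asks which genes differ in the gland when IRF6 is lost. Keratin genes of stressed or wound-edge epithelium and a small proline-rich protein gene lay lower in both libraries labelled Irf6 null. Irf6 itself and the ribonuclease P RNA-like gene Rprl3 lay higher in both. For Krt6b, Krt16, Irf6 and Rprl3 the difference was larger than the spread within the groups. Libraries of the same label lay far apart for Krt6a under the Irf6 null label and for Sprr2a2 under the wild-type label. Since no gene passed the adjusted threshold, the genes in this paragraph were chosen after their values were seen. Krt6b (ENSMUSG00000023041, chromosome 15, 101676023 to 101680287) stood at 44.9 ± 20.3 CPM (SD, n = 2) under the wild-type label and 0.14 ± 0.11 CPM (SD, n = 2) under the Irf6 null label. The 6 counts left under the Irf6 null label give a ratio of 249, with a 95% counting interval from 114 to 680. Krt16 (ENSMUSG00000053797, chromosome 11, 100246091 to 100248902) stood at 25.8 ± 3.95 CPM and 0.92 ± 0.39 CPM (SD, n = 2 each), a log2 fold change of -4.76 (SE 0.41). Krt6a stood at 55.6 and 52.7 CPM in the libraries labelled wild-type against 13.3 and 0.52 CPM in those labelled Irf6 null. Its log2 fold change was -2.95 (SE 1.19). Sprr2a2 was measured at 17.3 and 67.0 CPM against 2.27 and 0.90 CPM, a log2 fold change of -4.68 (SE 0.84). Krt6a and Krt6b, and the Sprr2a copies, are close paralogs between which estimated counts can be split, so the share of each is uncertain. Rprl3 (ENSMUSG00000088025, chromosome 8, 3803069 to 3803358) held 1 and 0 counts in the libraries labelled wild-type and 2973.64 and 3086.7 in those labelled Irf6 null, a ratio of 5150 with a 95% counting interval from 924 to 203453. Rprl3 is also uncertain, because its reads can be shared with other ribonuclease P RNA genes such as Rpph1, which stood at 2363 to 3896 CPM in the 4 libraries.

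By edgeR's quasi-likelihood test, 0 genes were higher and 0 lower under the Irf6 null label at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 197 genes, 72 higher and 125 lower, where 855 would be met by chance. The smallest adjusted p was 0.0585, for Rprl3, followed by 0.257 for Krt6b, 0.302 for Krt16 and 0.474 for Irf6. Limma-voom also called 0 genes, whereas DESeq2 called 20, 6 higher and 14 lower, of which 11 had over 90% of the higher group's signal from 1 library. The libraries labelled Irf6 null both exceeded both libraries labelled wild-type for 1527 genes and both lay below them for 1841. Together these were 19.7% of the genes tested, where random grouping gives 33.3%. Neither shortfall shows that genotype has no effect, since differences between libraries of the same label enter the spread. Dividing the libraries by replicate number gave 2844 genes at an unadjusted quasi-likelihood p under 0.05. With that number as a block, the labels still gave 209. The count of lower genes moved with 1 library: without the library labelled wild-type 1 it was 182, and 154 of the 184 genes called then were pseudogenes. Without wild-type 2 it was 13.

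The authors' deposited table of their own likelihood ratio comparison lists 166 genes, 132 with a positive and 34 with a negative log2 fold change. All 166 signs matched the libraries labelled wild-type over those labelled Irf6 null in the count table. The largest values in the authors' deposited table were 11.77 for Gm4518, 11.29 for Gm13292 and 11.13 for Atn1, and the smallest were -11.99 for Rprl3, -11.01 for Krt77 and -10.34 for Lce1i. The counts of Gm4518, Gm13292 and this Atn1 entry (ENSMUSG00000107478) were above 0 in wild-type 2 alone. For Atn1 this holds for that identifier only, since a symbol can have several. In counts, Krt77 was higher under the Irf6 null label by a ratio of 2140 (95% counting interval from 384 to 84543), and Lce1i, at 0 in both libraries labelled wild-type, was at least 86.4-fold higher. Of the signal under the Irf6 null label, 98.0% for Krt77 and 96.2% for Lce1i came from Irf6 null 1. Without that library the Krt77 ratio was 109 (95% counting interval from 18.6 to 4370) and Lce1i was at least 8.51-fold higher. In the authors' deposited table Irf6 has a log2 fold change of -2.96. Of its genes, 100 are annotated as pseudogenes, 96 of them positive. For 136 of the 166 genes, over 90% of the higher group's signal came from 1 library, which was wild-type 2 for 100 genes, Irf6 null 1 for 18, wild-type 1 for 17 and Irf6 null 2 for 1.

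Among 34 gene lists tested as sets, 8 were higher and 5 lower under the Irf6 null label by camera with a preset inter-gene correlation of 0.01. None of these 13 calls held with a correlation estimated per list, where the adjusted p ranged from 0.644 to 0.695 for them. That version of camera also rests on the few residual degrees of freedom of 4 libraries, so it had little power to call a list. For FGF signalling the estimated correlation, 0.0026, was below the preset 0.01, yet the unadjusted camera p rose from 0.000985 to 0.0725. A call lost with an estimated correlation therefore does not show that correlation among the genes undid it. Fry, which asks whether a list's genes move on balance in 1 direction, called 0 lists in either direction with a smallest adjusted p of 0.871. Over all alternatives, the adjusted p of these 13 lists ranged from 4.8e-128 to 0.891. No member of any list passed the adjusted threshold over all genes. Adjusted over the list alone, 5 members passed, namely Krt6b, Krt16 and Krt19 of the periderm list and Foxf1 and Foxf2 of the hedgehog list.

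**Figure D2:**
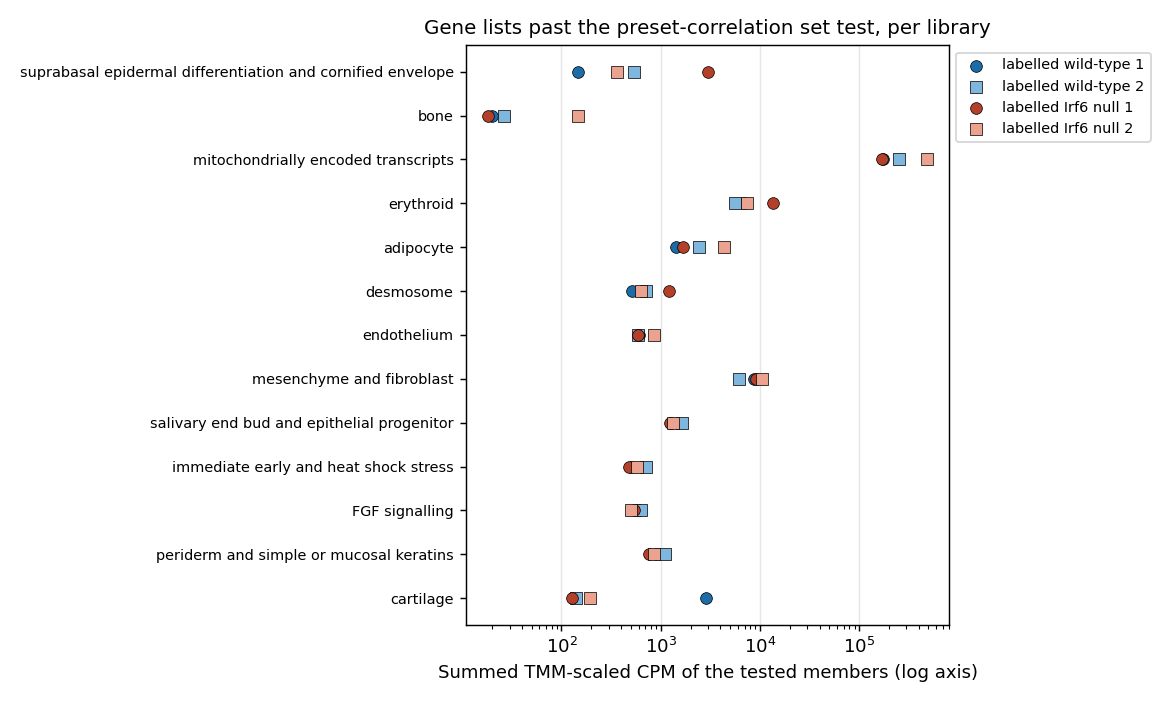
Each row is 1 of the 13 gene lists past the set test with a preset correlation, and each point is the summed TMM-scaled CPM of its tested members in 1 library (x axis, log scale), with colour and shape for the library's label. In several lists 1 library stands apart: cartilage at 2886 CPM in the library labelled wild-type 1 against 128 to 195 CPM in the others, and suprabasal epidermal genes at 2971 CPM in Irf6 null 1 against 146 to 535 CPM.

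Lists of surface epithelial genes were called in both directions. The suprabasal and cornified envelope list, the genes of the outer layers of the epidermis, was higher under the Irf6 null label, with 30 of 31 members above 0 and a median log2 fold change of 1.93 (camera adjusted p = 9.4e-18, and adjusted p = 0.694 with an estimated correlation). Its most abundant members, the suprabasal keratins Krt1 and Krt10, stood at 712 ± 836 and 275 ± 321 CPM (SD, n = 2) under the Irf6 null label against 127 ± 120 and 34.2 ± 34.4 CPM (SD, n = 2). The signal lay in 1 library: Krt1 was at 1302 CPM in Irf6 null 1 and at 121 CPM in Irf6 null 2, below the 212 CPM of wild-type 2. Without Irf6 null 1 the median was -0.06 and the camera adjusted p was 0.636. The desmosome list, the cell junctions that tie epithelial cells together, was also higher, with 9 of 12 members above 0 (median 0.39, camera adjusted p = 0.00344, and adjusted p = 0.694 with an estimated correlation). Dsp was measured at 192 ± 21.8 against 346 ± 194 CPM and Perp at 125 ± 56.0 against 172 ± 55.6 CPM (wild-type label first, SD, n = 2). Without Irf6 null 1 its median was -0.10 and the camera adjusted p was 0.863, and without wild-type 1 the adjusted p was 0.634 while the median stayed at 0.39.

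The periderm and simple or mucosal keratin list was lower under the Irf6 null label, with 12 of 17 members below 0 and a median log2 fold change of -0.35 (camera adjusted p = 1.1e-18, and adjusted p = 0.644 with an estimated correlation). Of the 13 lists called, it was the one that kept its preset-correlation call with each library left out in turn, with a median of -0.85 without Irf6 null 1. Its mean log2 fold change was -1.22, a larger drop than the median, with Krt6b at -8.14, Krt16 at -4.76 and Krt6a at -2.95. Krt19, a keratin of simple and duct epithelium, was also lower, at 36.8 ± 6.75 against 15.6 ± 2.81 CPM (SD, n = 2). These genes were chosen after their values were seen. The most abundant members moved little, Krt18 at 266 ± 78.6 against 258 ± 94.6 CPM and Krt8 at 258 ± 48.6 against 224 ± 13.4 CPM (SD, n = 2).

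Among genes of the branching gland, no member of the end bud or FGF lists passed a test, and the lists were called by camera with the preset correlation. The end bud and epithelial progenitor list had 20 of 24 members below 0, with a median log2 fold change of -0.16 (camera adjusted p = 0.0199, and adjusted p = 0.694 with an estimated correlation). Ehf, an epithelial ETS transcription factor, stood at 461 ± 128 against 431 ± 95.9 CPM and Dusp6, a phosphatase induced by FGF signalling, at 126 ± 21.7 against 97.8 ± 3.65 CPM (SD, n = 2). The FGF signalling list had 17 of 20 members below 0 with a median of -0.31 (camera adjusted p = 0.00304, and adjusted p = 0.694 with an estimated correlation). It shares Dusp6 with the end bud list, and Fgfr1 stood at 80.5 ± 32.0 against 76.7 ± 10.0 CPM (SD, n = 2). The end bud call was lost without any 1 of the 4 libraries, at camera adjusted p values from 0.0547 to 0.772. Its median was -0.31 without wild-type 1 and -0.27 without Irf6 null 1, but -0.04 without wild-type 2 and -0.07 without Irf6 null 2. Both the end bud and the FGF call were also lost with no filter on low counts, at adjusted p values of 0.0840 and 0.0572 and medians of -0.13 and -0.26. The FGF call was lost without wild-type 1 (0.565, median -0.20) or Irf6 null 2 (0.376, median -0.17). The immediate early and heat shock list was lower, with 17 of 24 members below 0 and a median of -0.20 (camera adjusted p = 0.000264, and adjusted p = 0.694 with an estimated correlation). Its most abundant members were Klf6 at 123 ± 31.4 against 107 ± 32.2 CPM (SD, n = 2) and Jund at 77.8 and 97.4 against 66.7 and 133 CPM. That call was lost without wild-type 2 (0.772), where the median was 0.07, or Irf6 null 1 (0.0607, median -0.30).

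Cartilage and bone genes stood apart in single libraries. The cartilage list was lower under the Irf6 null label, with 12 of 14 members below 0 and a median log2 fold change of -2.77 (camera adjusted p = 1.8e-10, and adjusted p = 0.694 with an estimated correlation). Col2a1, the main collagen of cartilage, was at 1265 CPM in wild-type 1, 0.65 CPM in wild-type 2, 1.46 CPM in Irf6 null 1 and 6.71 CPM in Irf6 null 2. Col11a1 stood at 202 ± 244 against 43.6 ± 23.2 CPM (SD, n = 2). Without wild-type 1 the cartilage median was 0.26 and the call was lost. The bone list was higher, with 9 of 10 members above 0 (median 1.34, camera adjusted p = 1.7e-05, and adjusted p = 0.694 with an estimated correlation). Ibsp, a bone matrix sialoprotein, was at 65.0 CPM in Irf6 null 2 against 0.38 to 2.23 CPM in the other libraries, while Runx2 lay between 8.28 and 15.7 CPM in the 4 libraries. Without Irf6 null 2 the bone median was -0.19 with a camera adjusted p of 0.487, and without wild-type 1 the adjusted p was 0.164 with a median of 1.18.

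Blood, fat, vessel and connective tissue lists were higher under the Irf6 null label. The erythroid list had 12 of 14 members above 0 with a median log2 fold change of 0.76 (camera adjusted p = 3.0e-08, and adjusted p = 0.694 with an estimated correlation), and Hbb-bs stood at 2585 ± 311 against 4231 ± 1884 CPM and Hba-a2 at 1560 ± 184 against 2733 ± 993 CPM (SD, n = 2). The adipocyte list had all 8 members above 0 (median 0.61, camera adjusted p = 0.000821, and adjusted p = 0.695 with an estimated correlation), with Fabp4 at 1155 ± 464 against 1803 ± 1187 CPM and Lpl at 242 ± 66.1 against 388 ± 271 CPM (SD, n = 2). The mitochondrially encoded transcripts had all 15 members above 0 (median 0.79, camera adjusted p = 3.7e-08, and adjusted p = 0.694 with an estimated correlation). The mitochondrial ribosomal RNA genes mt-Rnr1 and mt-Rnr2 made up 19.5% and 22.7% of the counts in wild-type 1 and 2 and 19.0% and 34.5% in Irf6 null 1 and 2, in CPM 20867 ± 7139 against 30829 ± 16968 for mt-Rnr1 and 180956 ± 44962 against 279231 ± 191299 for mt-Rnr2 (SD, n = 2). Without Irf6 null 2 the adipocyte median was -0.14 and the mitochondrial median -0.20, and both calls were lost, as they were without wild-type 1 (camera adjusted p 0.682 and 0.140, medians 0.32 and 0.54). The erythroid call was lost without Irf6 null 1 (0.0546, median 0.38).

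The mesenchyme and fibroblast list had 17 of 20 members above 0 with a median of 0.26 (camera adjusted p = 0.00116, and adjusted p = 0.695 with an estimated correlation). Col3a1 stood at 2045 ± 406 against 2644 ± 1.06 CPM and Col1a2 at 995 ± 296 against 1533 ± 320 CPM (SD, n = 2). The endothelium list had 17 of 19 members above 0 with a median of 0.27 (camera adjusted p = 0.00164, and adjusted p = 0.695 with an estimated correlation), with Cdh5 at 81.6 ± 2.33 against 113 ± 50.3 CPM (SD, n = 2) and Pecam1 at 82.4 and 89.5 against 77.1 and 133 CPM. Without wild-type 2 neither call held, at camera adjusted p values of 0.891 and 0.150, and without Irf6 null 2 they were 0.0597 and 0.821. The mesenchyme median was 0.08 without wild-type 2 and 0.24 without Irf6 null 2, and the endothelium median was 0.25 and 0.04. The endothelium call was also lost without wild-type 1 (0.0997), with a median of 0.33.

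The other 21 lists tested were not called by camera in the test without a block. In 8 of them (salivary duct, hedgehog, Notch, neurotrophic and EGF-family signals, p53, skeletal muscle, Schwann cell, macrophage) the median, the mean and the test differed in sign. The salivary acinar secretory list, which holds the products of the gland, had a camera adjusted p of 0.200, and its summed CPM followed the replicate number, at 16183 and 15433 in wild-type 1 and Irf6 null 1 against 48813 and 45320 in wild-type 2 and Irf6 null 2. With the replicate number as a block it was called higher, at a camera adjusted p of 0.0466, as was the basement membrane list at 0.0480. Without the block, neither was called with an estimated correlation (adjusted p = 0.917 and adjusted p = 0.695) or by fry (adjusted p 0.980 and 0.871). Over the alternatives the adjusted p of the acinar list ranged from 4.4e-07 to 0.980 and that of the basement membrane list from 0.0173 to 0.891. With the preset correlation the acinar list was also called higher without Irf6 null 1 or wild-type 2, but its median log2 fold change was -0.32 without wild-type 1 and -0.48 without Irf6 null 2. Its most abundant member, the submandibular gland protein gene Smgc, stood at 22212 ± 14255 against 19227 ± 13248 CPM, with Bpifa2 at 5027 ± 5215 against 4599 ± 3913 CPM (SD, n = 2). Whether these levels, or those of Adipoq (up to 242 CPM) and Lor (up to 83.1 CPM), belong to the labelled stage was not tested; these 2 genes were chosen after their values were seen. For the duct list the values were 598 ± 205 against 572 ± 161 CPM for Tfcp2l1 (SD, n = 2), beside Krt8 as above. The epithelial junction list gave Epcam at 245 ± 72.6 against 203 ± 14.0 CPM and Spint2 at 179 ± 63.4 against 159 ± 23.5 CPM (SD, n = 2). Basal epithelium gave Itga6 at 243 ± 15.4 against 226 ± 0.64 CPM and Dst at 103 ± 55.1 against 121 ± 12.2 CPM, and the basement membrane list gave Col4a1 at 695 ± 36.8 against 788 ± 239 CPM and Col4a2 at 338 ± 4.22 against 368 ± 108 CPM (SD, n = 2). The smooth muscle and myoepithelium list gave Cald1 at 179 ± 33.2 against 147 ± 7.08 CPM and Acta2 at 157 ± 2.48 against 150 ± 13.2 CPM, while the skeletal muscle list gave Myh8 at 997 ± 870 against 989 ± 877 CPM and Acta1 at 875 ± 686 against 940 ± 760 CPM (SD, n = 2). Proliferation genes gave Top2a at 226 ± 2.87 against 217 ± 86.0 CPM and Mki67 at 197 ± 56.4 against 238 ± 92.5 CPM, and the p53 list gave Ccng1 at 136 ± 12.5 against 159 ± 76.0 CPM, beside Perp (SD, n = 2).

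The signalling lists among these 21 were represented by their most abundant members, given as means over the 4 libraries. The levels were 48.2 CPM for Nfkbia and 47.5 CPM for Nfkb1 of the EDA and NF-kB list, 73.9 CPM for Smo and 56.0 CPM for Gas1 of the hedgehog list, and 41.6 CPM for Lgr4 of the WNT list, where Sfrp1 lay between 50.9 and 54.7 CPM. They were 72.8 CPM for Notch3 and 72.3 CPM for Notch2, 116 CPM for Tgfbr2 and 53.8 CPM for Tgfbr1, and 67.1 CPM for Rxra and 57.9 CPM for Dhrs3 of the retinoic acid list. Erbb3 and Egfr stood at 92.8 and 47.5 CPM, and B2m of the interferon list at 49.3 CPM, while Ifi27 lay between 39.5 and 169 CPM. Of the hypoxia and glycolysis list, Aldoa stood at 1016 CPM and Eno1 at 531 CPM. Within the hedgehog list Foxf1 was at 3.82 ± 0.28 against 0.54 ± 0.15 CPM and Foxf2 at 1.79 ± 0.38 against 0.19 ± 0.09 CPM (SD, n = 2), each with an adjusted p of 0.0431 over the list alone. The list as a whole had a median log2 fold change of 0.02 while camera placed it lower, at an adjusted p of 0.254.

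Markers of other cells that the tissue can hold are given as means or ranges over the 4 libraries. Mrc1 and Lyz2 of the macrophage list stood at 78.0 and 39.1 CPM over the 4 libraries, Gfra2 and Gap43 of the neuron list at 10.6 and 10.6 CPM, and Pmp22 of the glia list at 54.8 CPM. The melanocyte list had under 5 tested members and was not tested as a set; Mlph and Mitf stood at 29.7 and 6.92 CPM. As a library check, the Y-linked gene Ddx3y was at 54.0 to 106 CPM and Xist at 0.11 to 0.64 CPM in the 4 libraries, whatever their label.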

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

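The likelihood ratio tests and the restriction to protein-coding genes were chosen after seeing the data; the other alternatives were planned. With RLE scaling, limma-voom, the transcript classes left out, protein-coding genes only, and both stricter thresholds, 0 genes were higher and 0 lower under the Irf6 null label, as in the main test. Library size alone gave 1 higher (Rprl3) and 1 lower (Krt6b) and shifted the median log2 fold change of all genes by -0.15. The stricter filter gave 1 higher (Rprl3). DESeq2 gave 6 higher and 14 lower, the likelihood ratio test 9 higher and 8 lower, and no filter 176 higher and 465 lower, of which 486 had over 90% of the higher group's signal from 1 library and 319 were pseudogenes; the cause of the other calls was not tested. The likelihood ratio test with the replicate block on unrounded counts of all genes gave 34 higher and 133 lower; 164 of its 167 genes are in the authors' deposited table of 166, with fold changes within 0.067 of that table after the change of sign, against 75 shared genes of 119 called without the block. With 1 library left out, the counts ranged from 0 to 2 higher and from 0 to 182 lower; the lone library of a group was then assumed to vary like the other group. Without wild-type 1, 154 of 184 calls were pseudogenes.

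Irf6 was above 0 in every alternative run. It passed with DESeq2 (2.92), with no filter (2.92), with the likelihood ratio test (2.89), with that test and the replicate block (2.96) and without wild-type 1 (3.23, the highest of 2.69 to 3.23 with 1 library left out), and its adjusted p ranged from 4.3e-14 to 0.9998 over the alternatives; the cause was not tested.

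Of the lists, 0 were higher and 0 lower with an estimated correlation or fry, and no filter gave 3 lower, without the end bud and FGF lists; limma-voom gave 10 and 7. Leaving out 1 library gave 5 to 9 higher and 2 to 5 lower. The median log2 fold change then ranged from -4.27 to 0.26 for cartilage, -0.10 to 0.78 for desmosome, -0.21 to 0.22 for epithelial junction, -0.87 to 1.46 for skeletal muscle, -0.51 to 0.30 for cell cycle, -0.14 to 1.10 for adipocyte and -0.20 to 1.36 for mitochondrial transcripts. In these lists a call stood in 1 of the settings compared and the direction of the set test turned, without wild-type 1 for cartilage, Irf6 null 1 for desmosome, wild-type 2 for junction and skeletal muscle, and Irf6 null 2 for cell cycle, skeletal muscle, adipocyte and mitochondrial transcripts. Counting also turns where no call stood in either setting, over all alternatives the direction differed from the main test for 44 of 475 values of the 34 lists, 32 of them with 1 library left out, and for 95 of 1014 values of the 68 single genes followed besides Irf6, 66 of them with 1 library left out. Of the single genes, 7 values newly passed; of the lists, 52 values no longer passed and 21 newly passed, those that turned included.

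The replicate block gave 0 genes higher and 0 lower, 209 at an unadjusted p under 0.05, and 10 lists higher and 5 lower, with salivary acinar secretory and basement membrane genes added to those called higher. Same-numbered libraries had correlated deviations from their group means (0.17 across 17099 genes, which are not independent), but there are only 2 numbers and the labels do not say that a number marks a litter, so the libraries were not treated as paired. Depth limits wild-type 2, at 9676159 counts, the most.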

Other observations

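The tests in this part were chosen after the results were seen, apart from the quasi-likelihood test of the labelled groups. Some gene groups followed the replicate number and not the label. The salivary secretory genes summed to 16184 and 15434 CPM in wild-type 1 and Irf6 null 1 but to 48814 and 45320 CPM in wild-type 2 and Irf6 null 2. Prol1 stood at 3.12 and 2.83 CPM in the replicate 1 libraries and at 49.2 and 45.5 CPM in the replicate 2 libraries, Pip at 132 and 122 against 573 and 572 CPM, and Ucp1, the uncoupling protein of brown fat, at 101 and 100 against 711 and 1814 CPM. The nuclear RNA Malat1 went the other way, at 3079 and 2721 against 810 and 749 CPM. Dividing the 4 libraries by replicate number gave 2844 genes at an unadjusted p under 0.05 in the quasi-likelihood test, against 197 for the labels and 619 for the remaining division, although 0 genes passed the adjusted threshold in each of the 3. The likelihood ratio test called 468 genes for the replicate number, 17 for the labels and 114 for the remaining division, which points to a structure of the samples along the replicate number.

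Single libraries held further tissue genes. In wild-type 1 the thyroid hormone precursor gene Tg was at 314 CPM against 1.52 to 2.00 CPM in the others, the airway secretoglobin Scgb3a2 had 1002 counts against 0 to 2, and Myh4, a fast skeletal muscle myosin, was at 115 CPM against 0.17 to 1.03 CPM. The thyroid list summed to 328 CPM there against 3.91 to 7.62 CPM. For the airway and ciliated list the sums were 135 against 23.6 to 43.8 CPM. Unlike Myh4, the skeletal muscle list was not particular to wild-type 1. It summed to 7946 CPM in wild-type 1 and 7393 CPM in Irf6 null 2, against 1966 CPM in wild-type 2 and 2495 CPM in Irf6 null 1. In Irf6 null 2, Irf4 was at 99.5 CPM against 1.63 to 2.32 CPM. Early suprabasal genes summed to 65.1 and 335 CPM in wild-type 1 and 2 and to 2193 and 206 CPM in Irf6 null 1 and 2, and late cornified genes to 0.59 and 36.9 and to 1580 and 85.6 CPM. The authors' deposited list of Mist1 targets had 17 of 28 tested members above 0 (camera adjusted p = 0.470, and adjusted p = 0.827 with an estimated correlation). The wound-type keratins Krt6a, Krt6b and Krt16 summed to 109 and 140 CPM in wild-type 1 and 2 and to 14.7 and 1.23 CPM in Irf6 null 1 and 2.

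Irf6 was higher in both libraries labelled Irf6 null. The lower of them held 6.21 times the Irf6 of the higher library labelled wild-type, but this ratio restates the pattern and does not test exchanged labels, which stay open. A larger share of epithelium under the Irf6 null label is argued against by the epithelial junction list, whose median log2 fold change was -0.0494 (SD of members 0.31) against 2.90 for Irf6. Also open is that the labels are right and the mutant allele is transcribed above the intact one. Loss of IRF6 is known to lower the ratio of late cornified to early suprabasal genes in skin. That ratio was 3.77 times higher in the lower library labelled Irf6 null than in the higher one labelled wild-type. Carried over from skin, this is the opposite of what right labels predict and the direction that exchanged labels predict. Both lists were added after the values of such genes had been seen, however. Early suprabasal genes also summed to between 65.1 and 2193 CPM in single libraries, and whether skin was taken along was not tested. Groups of 2 cannot give an exact permutation p under 0.333, so the ratio decides neither explanation.

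In wild-type 2, 267 processed pseudogenes with at least 20 counts were at least 10 times higher than in any other library, against 0 in wild-type 1, 3 in Irf6 null 1 and 0 in Irf6 null 2, and they held 0.666% of its counts. Genomic DNA is argued against by olfactory and vomeronasal receptor genes, which were at 0.977 times the highest of the other libraries. Whether reads shared with the parent genes were assigned to the pseudogenes stays open: 11.2% of these pseudogenes had a count that was whole to the 2 decimals given, which shared reads would rarely give, near the 12.6% of pseudogenes with as many counts in wild-type 1. No biological explanation was tested, since 1 library shows the pattern. Reads from another organism were not examined either. Separately, the mouse genes Hoxb6 and Hoxa10 had 21 and 18 counts in wild-type 2 against 0 to 1 elsewhere. These counts do not bear on that question, and their source was not tested.

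Cartilage genes stood apart in wild-type 1 and epidermal genes in Irf6 null 1, with Col2a1 at 1265 CPM and Krt1 at 1302 CPM there. A genotype difference is argued against as the source of the high cartilage and early suprabasal values, which the other library of the same label did not share. For cartilage the lower library labelled wild-type held 0.719 times the summed CPM of the higher library labelled Irf6 null. For early suprabasal genes the corresponding ratio of the lower Irf6 null to the higher wild-type library was 0.615. With 2 libraries per group, this overlap cannot exclude a smaller genotype difference in these genes. Whether neighbouring cartilage and skin were taken along with these libraries was not tested and stays open. Late cornified genes stood at 0.906% and 11.01% of early suprabasal CPM in wild-type 1 and 2 and at 72.0% and 41.5% in Irf6 null 1 and 2 (exact permutation test, two-sided, p = 0.333, the smallest that 2 against 2 libraries allow), so for them a genotype difference stays open.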
